A study of Mus musculus with 12 samples.

How the data were processed

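Gene expression was measured by single-colour microarray in microglia from male mice aged 8 weeks, with 6 groups of 2 samples each. Per the labels' protocols, microglia were enriched by magnetic sorting for CX3CR1, RNA was extracted with Trizol, and the labelled RNA carried the dye Cy3. The groups were 3 genotypes (wild type, overexpression of ZEB1, knock-down of ZEB1), each before and after transient middle cerebral artery occlusion (tMCAO). Samples were assigned to groups from their labels alone. The labels name the replicates as separate samples but do not state whether they came from separate animals, so each p-value measures only the spread between these samples, which may be technical.

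Per the file headers, the scanner files were written by Agilent Feature Extraction 11.5.1.1, whereas the submitters' processing notes name Agilent Feature Extraction 9.1. The scanner files hold linear fluorescence intensity per spot, which the authors deposited after background subtraction and spatial detrending by that software, per the file headers. The same files carry yes or no marks for each spot, a unit of the kind "other", which per the file headers state whether the spot was well above background, saturated, non-uniform or an outlier among its replicate spots. The value tables that the authors deposited hold log2 values. Set against the scanner files, each column equalled the log2 signal of a single array minus a constant, with a 75th percentile of 0 and medians from -3.77 to -3.05, so their scale, centring and direction are known. The 2 columns of ZEB1 knock-down after tMCAO each matched the scanner file of the other replicate of that group (correlation across probes with their own file 0.975). Group results are unaffected by that exchange because both arrays belong to the same group. The scanner files were used for all results, and the value tables served as an alternative. Genome build and aligner play no part in these arrays.

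The 12 arrays were of 2 designs. Wild type and ZEB1 overexpression after tMCAO were hybridised to a slide of 4 arrays with 55681 probes, and the other 4 groups to a slide of 8 arrays with 56605 probes. Each design was a single slide with a single scan date. The slides are named by the number of their arrays in this series. Comparisons were tested only between groups on the same slide, so slide and scan date do not differ within any tested pair of groups, and no value within a second slide exists. For a pair of groups on different slides the slide and the group cannot be told apart, and only values without a test are given. The designs share 30629 probes by name.

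Each array held 59305 spots that were not controls. The 75th percentile of the signal ran from 1078 to 1515 intensity units on the 4-array slide and from 2566 to 3702 on the 8-array slide. Between 60.4% and 73.9% of spots were well above background, and 3 spots on 1 array were saturated. Spots marked by the scanner software as non-uniform or outlying were left out. They made up 1.03% to 3.29% of the spots on the wild type and ZEB1 knock-down arrays before tMCAO and 7.49% to 23.7% on the other 8 arrays. On the 8-array slide the share went with the side, with 18.2% to 23.7% in columns 1 and 2 and the lower shares in columns 3 and 4. The SD of the negative controls differed likewise, with 9.20 to 14.4 against 4.59 to 6.65. Bright spots were marked more often than dim ones. As a result some bright genes rest on 1 array of a group, as stated beside them. The number of arrays limits the precision.

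The processed intensity was converted to log2, the 75th percentile of each array was subtracted, and spots of the same probe were averaged. All levels are therefore log2 values relative to the 75th percentile of the array. Probes were named from their accessions through the RefSeq gene table, without versions. This named 26762 probes (48.1%) of the 4-array design and 33767 (59.7%) of the 8-array design, and the other probes kept the accession or identifier of the file. A probe was kept if it was well above background on every array of at least 1 group of its slide, and a gene was represented by its probe with the highest mean level. This left 27935 genes or accessions on the 4-array slide, of which 16335 carried a gene symbol, and 30525 on the 8-array slide, of which 17954 did. Where a named gene had further probes that went the opposite way, this is stated.

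Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all groups of a slide in the same fit. The p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. All errors beside log2 fold changes are standard errors (SE). A further contrast asked whether the difference between ZEB1 overexpression and wild type was itself different after tMCAO. It was fitted over the shared probes on all 12 arrays with the 6 group means, so that a probe's constant offset between the designs cancels within each time, but not a difference in scale between them. In a group where no array had a probe well above background, the gene has only a bound. It is given as at least a certain fold, from the mean of the bright group against the mean, over the arrays of the dim group, of the higher of the lowest signal well above background and the probe's own signal, and no fold is given where that bound falls under 1.

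There were 25 gene lists covering microglial states, inflammation, signalling pathways, metabolism and the markers of other brain and blood cells, with 427 members, of which 426 matched a gene and 6 belong to 2 lists. They were tested with camera in its pre-ranked form (limma) on the moderated statistics, with the preset correlation between genes of 0.01 and adjustment over the lists of a comparison. A member counted as measured if its probe passed the filter and had a value in each group compared. Bright members with marked spots can therefore be missing, and counts and medians cover measured members only. Camera was also run with the correlation estimated from the arrays, under which no list passed in any comparison. The degrees of freedom of that version are the number of arrays less the number of groups. With so few, a list could hardly pass after adjustment, so its failure there does not decide whether the list changed. The estimates, themselves from few arrays, were often far above the preset 0.01. For overexpression against wild type before tMCAO they ran from 0 for alternative activation to 0.907 for the interferon response. Where the genes of a list correlate more than the preset, the camera p-values given here are too small. The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are Zeb1, Tgfb1 and Cxcl1, the 6 largest rises and 6 largest falls past the threshold with arrays of the groups not overlapping and with a gene symbol that is not a clone or locus identifier, and the 2 members with the smallest p from each list past the threshold or with at least 2 members past it. Where no gene passed, the 4 largest differences in each direction at an unadjusted p under 0.01 stand in as values. Ddx58, Gbp2, Isg15, Rsad2, Cybb, Tlr4 and Pard6b are named outside this rule and were chosen after their values were seen.

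The procedure was tested on simulated data with 200 genes changed by known folds, 50 at each size. Of genes changed 4-fold, 70.0% were recovered for overexpression against wild type before tMCAO (25162 genes), 62.0% for knock-down against wild type (30293 genes), 66.0% for overexpression against knock-down (25167 genes), 100% for overexpression against wild type after tMCAO (22072 genes), 68.0% for knock-down after against before tMCAO (24646 genes) and 36.0% for the difference of differences (15647 genes). At 2-fold the recovered shares were 14.0%, 10.0%, 16.0%, 18.0%, 10.0% and 0% in the same order. Unchanged genes called were 3, 2, 8, 16, 8 and 7. The simulated noise was independent between genes and arrays, without deviations of a whole array, so recovery in the real arrays may be lower. The alternatives covered background correction, scaling between arrays, the source of the values, the filter on dim probes, the choice of probe, the replicate number as a block, the variance model, the arrays in the fit, the threshold, the spots marked by the scanner software and each array left out in turn. Pairs of groups on different slides were left out of all tests because the slide cannot be separated from the group.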

Results

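Microglia, the resident macrophages of the brain, were enriched by magnetic sorting for the fractalkine receptor CX3CR1 and profiled on expression arrays. The mice were wild type, overexpressed the zinc-finger transcription factor ZEB1, which is known as a repressor of epithelial genes, or carried a ZEB1 knock-down. Cells were taken before or after tMCAO, a stroke model in which blood flow through a brain artery is blocked and then restored. The 6 groups held 2 samples each, 12 arrays in total, 4 of them on one slide and 8 on another. Across genes, which are not independent replicates, the arrays of a group correlated at 0.975 to 0.990. The design names the comparison of the 3 genotypes before tMCAO and again after it.

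Zeb1 itself, the manipulated gene, was examined first. On the 8-array slide its brighter probe lay at -0.57 and -0.59 in the wild type arrays before tMCAO, at -0.28 and -0.36 in the arrays labelled ZEB1 overexpression, and at -0.11 and -0.79 in the arrays labelled ZEB1 knock-down (log2 relative to the array's 75th percentile). With all spots kept, the log2 difference from wild type was 0.26 for overexpression (95% interval -0.30 to 0.82, limma adjusted p = 0.788) and 0.13 for knock-down (95% interval -0.43 to 0.69, adjusted p = 0.997). Those intervals exclude a doubling in the overexpression arrays and a halving in the knock-down arrays. The dimmer probe gave 0.15 and 0.06. After tMCAO, the Zeb1 probe of the 4-array slide lay at 0.12 and 0.41 in wild type and at -0.08 and 0.56 in overexpression, a log2 difference of -0.02 (95% interval -0.72 to 0.68, adjusted p = 0.974). Both wild type spots of that probe were marked by the scanner software, so the gene has no value with marked spots left out. Where the probes lie relative to an introduced or targeted sequence is not given in the sources used here, and groups are named as labelled. The probe levels show no change of the kind the labels name, and whether labels or samples were mixed up was not tested.

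**Figure D1:**
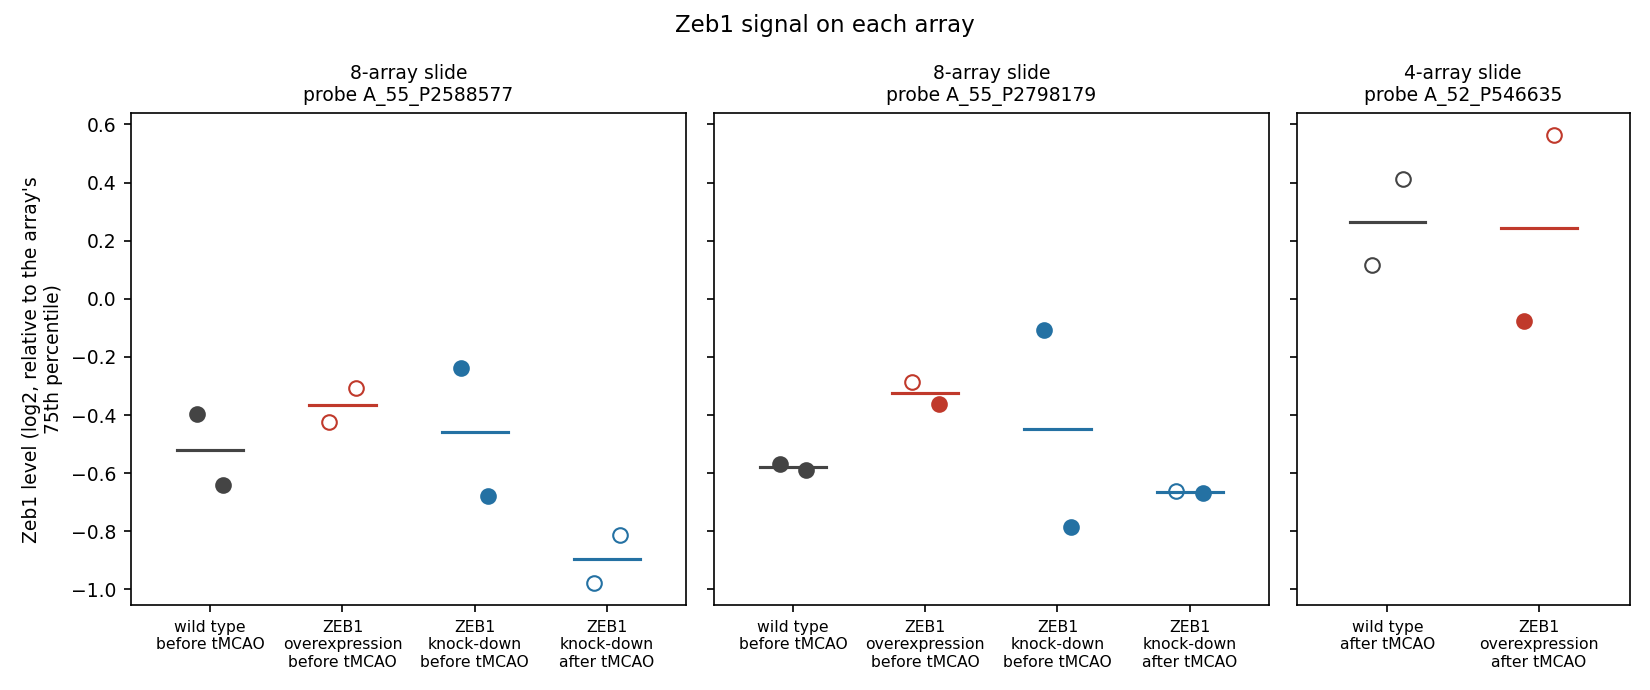
Zeb1 level on each array by probe, in log2 relative to the 75th percentile of the array, with filled points for spots used, open points for spots marked by the scanner software as non-uniform or outlying, and bars for group means. The brighter probe of the 8-array slide ran from -0.79 to -0.11 over all groups, with the overexpression arrays before tMCAO at -0.28 and -0.36.

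The first comparison before tMCAO was of ZEB1 overexpression with wild type. On the 8-array slide each group occupied a single row, so the row differs between wild type (row 1) and both other genotypes (row 2) before tMCAO. The overexpression arrays before tMCAO lay in columns 1 and 2, and those of wild type and knock-down in columns 3 and 4. Side and share of marked spots therefore cannot be told apart from overexpression before tMCAO. Among the largest differences between overexpression and wild type before tMCAO were Acod1, the enzyme that makes itaconate, with a log2 difference of 2.84 ± 0.59 (adjusted p = 0.242) and Hcar2, a receptor for hydroxybutyrate and niacin, at 2.47 ± 0.48 (adjusted p = 0.256). Il1rn, which encodes the interleukin-1 receptor antagonist, was at 3.84 ± 0.94 (adjusted p = 0.316), all 3 with n = 2 arrays per group. The odorant receptor gene Olfr224 was at least 13.6-fold higher against a wild type level not well above background (adjusted p = 0.215). On the other side stood Galnt3, a mucin-type glycosyltransferase, at least 1.78-fold lower (adjusted p = 0.115), Slc4a1, the red cell anion exchanger, at least 1.27-fold lower, and Sgo2b at least 1.11-fold lower, all 3 not well above background in the overexpression arrays. Zfp990, a zinc-finger gene, was at -2.32 ± 0.23 on 1 overexpression array (adjusted p = 0.215). The chemokine gene Cxcl1 differed by -0.79 ± 0.81 and the growth factor gene Tgfb1 by -0.23 ± 0.30. None of these differences passed. Limma called 0 of 25162 genes, with 2712 genes (10.8%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.115. Camera called 0 of 25 gene lists (smallest adjusted p = 0.384).

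ZEB1 knock-down was then compared with wild type before tMCAO. The erythroid globin gene Hba-x was at least 1.79-fold lower (adjusted p = 0.393), the interferon-inducible gene Ifi202b at least 2.29-fold lower, and the transcription cofactor gene Vgll1 at least 1.52-fold lower, all not well above background in the knock-down arrays. Usp24, a ubiquitin-specific protease gene, was at -2.43 ± 0.36 (adjusted p = 0.411). In the opposite direction lay the kinase gene Alpk2 at least 1.73-fold higher (adjusted p = 0.168), Clrn2 at least 2.66-fold, Clca3a2 at least 2.11-fold, and the vomeronasal receptor gene Vmn1r51 at 2.85 ± 0.77 (adjusted p = 0.411). Tgfb1 differed by -0.48 ± 0.29 and Cxcl1 by -0.76 ± 0.82. No difference passed. Limma called 0 of 30293 genes, with 2651 (8.75%) at an unadjusted p under 0.05, and camera called 0 of 25 lists (smallest adjusted p = 0.140).

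In the direct contrast of ZEB1 overexpression with knock-down before tMCAO, hormone and kallikrein genes, typical of pituitary and salivary gland, were among the lowest values. Gh, which encodes growth hormone, was at -4.86 ± 0.78 (adjusted p = 0.227), and the kallikrein genes Klk1b4, Klk1b8 and Klk1b22, encoding secreted serine proteases, were at -6.03 ± 1.33, -4.52 ± 1.11 and -4.36 ± 0.97. All 4 rested on 1 overexpression array. Klk1b4 was not well above background on that array, so its fitted value is not a measured fold. With all spots kept the overexpression replicates lay far apart (Klk1b4 at -7.90 and 0.16, Gh at -1.42 and 4.39). With marked spots kept, the values were -1.95 for Gh, -2.0 for Klk1b4, -1.21 for Klk1b8 and -1.28 for Klk1b22. Higher in value were Acsm1, an acyl-CoA synthetase gene, at 2.68 ± 0.62 (adjusted p = 0.249), the trefoil factor gene Tff2 at least 4.21-fold (adjusted p = 0.151) and Olfr224 at least 13.4-fold (adjusted p = 0.211), whereas Tcl1b4 was not well above background in the knock-down arrays and has no bound. Tgfb1 differed by 0.25 ± 0.30, with its second probe going the opposite way, and Cxcl1 by -0.03 ± 0.81. Limma called 0 of 25167 genes, with 3343 (13.3%) at an unadjusted p under 0.05, and camera called 0 of 25 lists (smallest adjusted p = 0.328).

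Both genotype comparisons before tMCAO used the same wild type arrays. Over the 25153 genes measured in both, the log2 fold changes correlated at 0.527 across genes, against 0.488 in 100 simulations of unchanged groups with shared controls, and the covariance was 0.148 against a simulated 0.0569 (highest simulated value 0.0626). The signs matched for 55.1% of genes, against 66.1% in the simulations. No gene was called in both. The simulations already hold the shared wild type arrays, so sharing as simulated does not account for the excess in covariance. Wild type arrays that varied more than simulated could raise it, as could the row, which sets wild type apart from both other genotypes. These cannot be told apart here. The wild type arrays were not split between the comparisons, since each part would hold 1 array.

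The comparison of ZEB1 overexpression with wild type was repeated after tMCAO, on the 4-array slide. Genes of the interferon response were higher in the overexpression arrays. Of 21 members 12 were measured. Of these 6 rose and none fell, 10 rose when adjusted over the list alone, and all 12 had a positive log2 fold change (median 1.86, camera adjusted p = 4.82e-12). With an estimated correlation the list did not pass (adjusted p = 0.430 with an estimated correlation). Ifit2, an interferon-induced antiviral gene, rose by 4.18 ± 0.32 (adjusted p = 0.0105) on 1 overexpression and 2 wild type arrays, and Ifi44 rose by 2.71 ± 0.27 (adjusted p = 0.0111). The other members past the threshold were Ddx58, a sensor of viral RNA, Gbp2, a guanylate-binding protein gene, Isg15, a ubiquitin-like modifier, and Rsad2, which encodes viperin. Their log2 fold changes ran from 1.72 in Isg15 to 3.04 in Gbp2, with Gbp2 and Rsad2 on 1 overexpression array. Outside the list, Ifi214, an interferon-activated gene, rose by 4.71 ± 0.77 (adjusted p = 0.0326) and Slfn4, a Schlafen family gene of myeloid cells, by 4.0 ± 0.37 (adjusted p = 0.0104).

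Inflammatory cytokines and enzymes moved the same way in these arrays. Of 12 measured members, 4 rose (Nos2, Tnf, Cybb and Tlr4), 7 rose when adjusted over the list alone, and all 12 had a positive fold change (median 1.1, camera adjusted p = 9.03e-09, adjusted p = 0.430 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose by 1.96 ± 0.28 (adjusted p = 0.0226) and Tnf by 1.54 ± 0.24 (adjusted p = 0.0287). Of 15 chemokine genes, 2 rose and 7 rose when adjusted over the list alone (median 0.89, camera adjusted p = 0.000702, adjusted p = 0.430 with an estimated correlation). The chemokine median ran from 0.04 to 1.06 over the alternatives and left-out arrays, and the list did not pass in 1 of 4 fits with an array left out. Cxcl13, a B cell attractant, rose by 3.62 ± 0.25 (adjusted p = 0.00387), and Cxcl10, a T cell attractant induced by interferon, by 3.45 ± 0.39 (adjusted p = 0.0285) on 1 array per group, with an SE taken from the spread of other genes, and by 2.56 with marked spots kept (adjusted p = 0.0349). Cxcl1, a neutrophil attractant, was at 1.16 ± 0.28 and did not pass (adjusted p = 0.0841). Among 10 genes of alternative activation, Il10, an anti-inflammatory cytokine gene, was the 1 that rose, also when adjusted over the list alone. It rose at least 7.27-fold from a wild type level not well above background (adjusted p = 0.020), and the list had a median of 0.62 (camera adjusted p = 0.0156, adjusted p = 0.596 with an estimated correlation).

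Markers of other cells were measured in the same arrays. Lymphocyte markers had a positive log2 fold change in all 13 measured members (median 0.62, camera adjusted p = 0.00201, adjusted p = 0.596 with an estimated correlation), with 0 past the limma threshold over all genes and 1 when adjusted over the list alone. With an array left out, the lymphocyte median ran from 0.09 to 1.34, the higher value without overexpression replicate 1, and the list did not pass in 1 of 4 fits. Examples were Cd3g, a T cell receptor subunit, at 1.99 ± 0.39 on 1 array per group (adjusted p = 0.0820) and Ms4a1, a B cell antigen, at 1.20 ± 0.46 (adjusted p = 0.206). Of 8 neutrophil markers 1 rose, over all genes and when adjusted over the list alone, Elane, which encodes neutrophil elastase, by 2.01 ± 0.37 (adjusted p = 0.0463). The neutrophil list had a median of 0.46 (camera adjusted p = 0.0156, adjusted p = 0.430 with an estimated correlation). Monocyte and border macrophage markers passed as a list (median 0.59 over 10 members, camera adjusted p = 0.0168, adjusted p = 0.430 with an estimated correlation). The monocyte list had 0 members past the limma threshold, also when adjusted over the list alone, and the chemokine receptor gene Ccr2 was at 0.69 ± 0.26 and the chitinase-like gene Chil3 at 0.86 ± 0.31 on 1 wild type array. Endothelial and mural markers lay lower in all 10 measured members (median -0.92, camera adjusted p = 0.000702, adjusted p = 0.430 with an estimated correlation), 0 past the limma threshold over all genes and 6 when adjusted over the list alone. Des, an intermediate filament gene of pericytes and smooth muscle, was at -1.27 ± 0.25 (adjusted p = 0.0543) and Cdh5, the vascular endothelial cadherin, at -1.26 ± 0.27 (adjusted p = 0.0657).

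Immediate early and tissue dissociation genes passed as a list (14 members, 13 positive, median 0.63, camera adjusted p = 0.000613, adjusted p = 0.596 with an estimated correlation) with 0 members past the limma threshold, also when adjusted over the list alone. The transcription factor genes Atf3 and Klf6 were at 1.28 ± 0.33 and 1.13 ± 0.32, Klf6 on 1 overexpression array. Activated microglia genes passed (median 0.51 over the 7 measured of 18 members, camera adjusted p = 0.0270, adjusted p = 0.596 with an estimated correlation), with 0 members past the limma threshold and 2 when adjusted over the list alone. That list did not pass in 3 of 12 alternatives, among them the one with marked spots kept (camera adjusted p = 0.179). Alternative activation genes, neutrophil markers and monocyte markers each did not pass in 1 of 12 alternatives. Over the alternatives and left-out arrays, the medians ran from 0.11 to 0.64 for neutrophil markers, 0.28 to 0.67 for monocyte markers, 0.31 to 0.88 for alternative activation, 0.37 to 0.78 for immediate early genes and -0.0049 to 1.37 for activated microglia. Each of these 5 lists did not pass in 2 of 4 fits with an array left out. Axl, a receptor for dying cells, was at 1.38 ± 0.31 and Ch25h, cholesterol 25-hydroxylase, at 1.37 ± 0.31. Homeostatic microglia genes had a median of -0.06 with a mean of 0.08 and a test direction upward (8 members, camera adjusted p = 0.498), the TGF-beta pathway 0.19 (14 members, adjusted p = 0.269), and epithelial-mesenchymal transition and ZEB1 repression targets -0.21 (16 members, adjusted p = 0.498). Of the last, Pard6b, a cell polarity gene, fell to a level not well above background (adjusted p = 0.0235). Tgfb1 was at 0.46 ± 0.40 (adjusted p = 0.562).

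**Figure D2:**
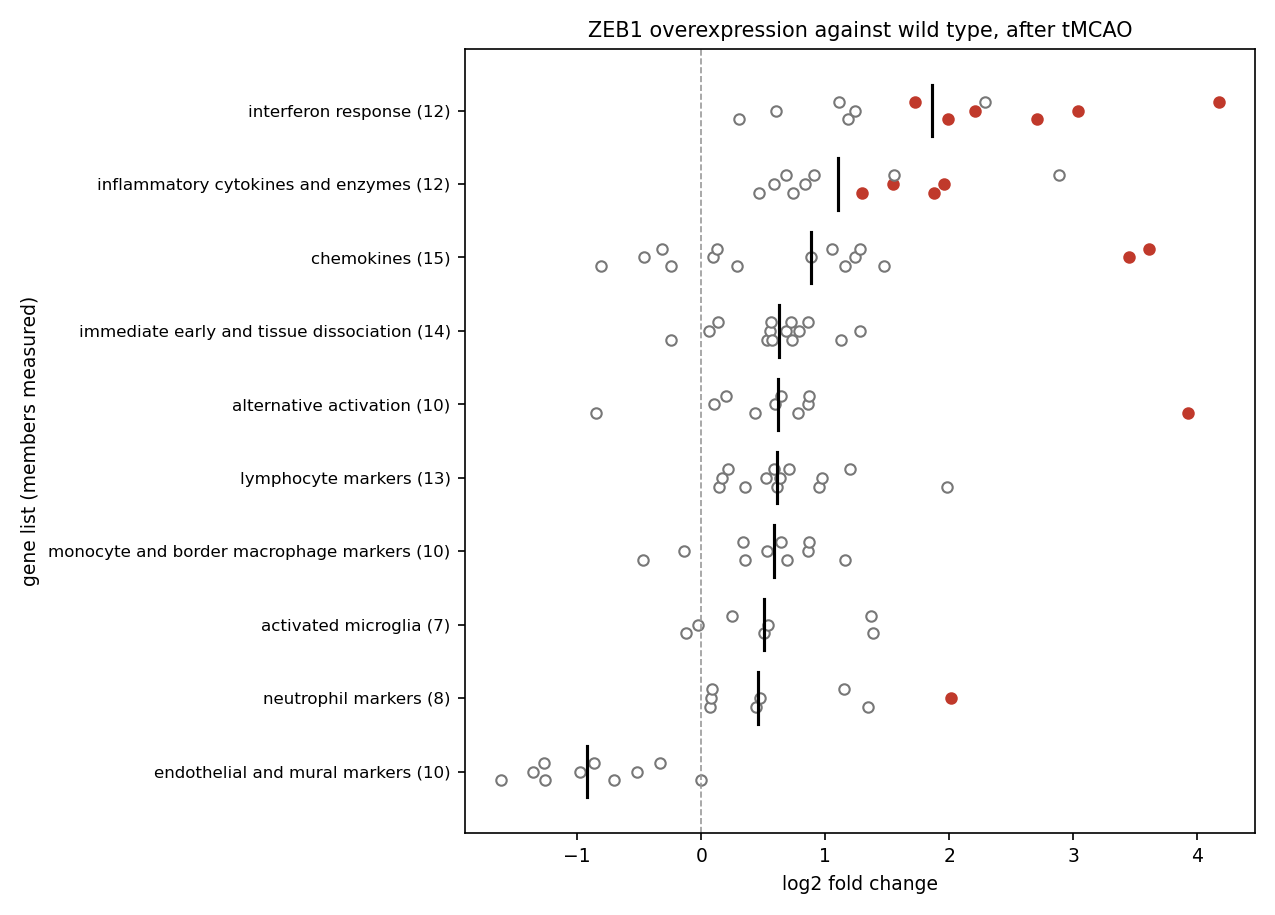
Log2 fold change of each measured member of the gene lists past the camera threshold, ZEB1 overexpression against wild type after tMCAO, with filled points for genes past an adjusted p of 0.05, open points for the others, vertical bars for list medians and the number of measured members in brackets. Interferon response genes had a median of 1.86 and endothelial and mural markers a median of -0.92.

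Limma called 510 of 22072 genes after tMCAO, 348 higher and 162 lower in ZEB1 overexpression (68.2% higher), and 4592 genes (20.8%) had an unadjusted p under 0.05. Other large rises were S100a7l2, an S100 calcium-binding protein gene, at least 5.11-fold (adjusted p = 0.00329), Cd69, an early activation antigen of leukocytes, by 3.99 ± 0.26 (adjusted p = 0.00341), and Gdpd3, a phosphodiesterase gene, by 4.25 ± 0.39 on 1 array per group, again with the SE of other genes (adjusted p = 0.0193). With marked spots kept, Gdpd3 was at 2.20 and did not pass (adjusted p = 0.242). S100a7l2 varied widely between the 2 wild type arrays before tMCAO on the other slide (log2 SD 5.35). Its rise may therefore reflect single samples. Of the 510 calls, 4 had no replicate value in either group and so no spread of their own. Largest among the falls past the threshold were Krtap5-4, a keratin-associated protein gene, by -3.22 ± 0.52 (adjusted p = 0.0316), Cnfn, which encodes cornifelin, by -2.87 ± 0.31 on 1 wild type array (adjusted p = 0.0182), and Med12l, a Mediator subunit gene, by -2.60 ± 0.30 (adjusted p = 0.0144). To levels not well above background fell Olfr429 at least 1.85-fold, Afm, which encodes afamin, at least 3.52-fold, and Zp3, an egg coat protein gene, at least 2.01-fold. In 100 of the 510 genes, a group was not well above background. The other 15 lists did not pass (camera adjusted p from 0.184 to 0.976). Neuron markers (median -0.39, adjusted p = 0.0256) and oligodendrocyte lineage markers (median -0.49, adjusted p = 0.0252) passed, both lower in overexpression, when marked spots were kept. Both wild type arrays lay in row 1 of the slide and both overexpression arrays in row 2, so row and genotype cannot be told apart. The count was 54 without wild type replicate 1, 115 without wild type replicate 2, 1079 without overexpression replicate 1 and 857 without overexpression replicate 2, and 0 with no filter on dim probes (limma, 4123 of 31284 genes at an unadjusted p under 0.05). With each array left out, all measured called genes, which are called for agreement between arrays, kept their direction, with fold changes at a median of 0.971 to 1.02 of their size and SEs at 1.16 to 1.40 times theirs.

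Microglia with ZEB1 knock-down were compared after against before tMCAO, the contrast that addresses the injury within a genotype. The arrays after tMCAO lay in row 1, columns 1 and 2, of the slide and those before tMCAO in row 2, columns 3 and 4. Row, side and the share of marked spots (20.8% and 23.5% after, 1.87% and 1.03% before) therefore went with time. Cell cycle genes rose in nearly all measured members. Of 23 members 15 were measured. Of these 14 rose, also when adjusted over the list alone, and all 15 had a positive fold change (median 2.79, camera adjusted p = 8.96e-10, adjusted p = 0.385 with an estimated correlation). Birc5, a mitotic survivin gene, rose by 3.92 ± 0.23 (adjusted p = 0.00228) and Ccnb2, a mitotic cyclin, by 4.54 ± 0.32 (adjusted p = 0.00303). The mitotic kinase gene Pbk rose by 6.22 ± 0.92 (adjusted p = 0.0170) and the checkpoint kinase gene Bub1 at least 53.9-fold, both on 1 array after tMCAO. Activated microglia genes rose in 8 of 11 measured members, 10 when adjusted over the list alone (median 2.64, camera adjusted p = 2.19e-06, adjusted p = 0.318 with an estimated correlation). Cst7, a cystatin of phagocytic microglia, rose by 5.46 ± 0.24 (adjusted p = 0.00228) and Gpnmb, a lysosomal glycoprotein gene, by 3.22 ± 0.21 (adjusted p = 0.00392), each on 1 array after tMCAO. Homeostatic microglia genes had a median of 0.53 over 9 members and did not pass (camera adjusted p = 0.255), but passed with marked spots kept (adjusted p = 0.0297). Over all genes 2 members were higher, and 3 were higher and 1 lower when adjusted over the list alone. The members past the threshold were Olfml3, by 1.94 ± 0.36 (adjusted p = 0.0218), and Cx3cr1, the gene of the sorting marker, by 1.41 ± 0.33 (adjusted p = 0.0395).

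In the same arrays, complement genes rose in 9 of 11 members, also when adjusted over the list alone (median 1.76, camera adjusted p = 2.34e-06, adjusted p = 0.308 with an estimated correlation). Among them were C4b by 1.86 ± 0.19 (adjusted p = 0.00549) and Serping1, an inhibitor of the first complement proteases, by 1.76 ± 0.20 (adjusted p = 0.00686). Chemokines rose in 9 of 15 members, with 9 higher and 1 lower when adjusted over the list alone (median 2.14, camera adjusted p = 0.000842, adjusted p = 0.385 with an estimated correlation). They included Ccl12 by 3.82 ± 0.38, Cxcl16 by 3.09 ± 0.25 on 1 array after tMCAO and Cxcl1 by 4.69 ± 0.81 (adjusted p = 0.0181). Of 9 alternative activation genes 6 rose, also when adjusted over the list alone (median 1.67, camera adjusted p = 0.00661, adjusted p = 0.308 with an estimated correlation). The scavenger receptor gene Cd36 rose by 1.96 ± 0.26, and Il4ra, which encodes the interleukin-4 receptor, by 2.43 ± 0.20 on 1 array after tMCAO, with its second probe going the opposite way. Over the alternatives and left-out arrays, the medians ran from 0.77 to 2.43 for alternative activation, which did not pass in 1 of 8 fits with an array left out, from 1.43 to 3.25 for activated microglia and from 1.75 to 2.92 for cell cycle genes. Antigen presentation genes passed narrowly (3 of 10 rose, also when adjusted over the list alone, median 1.1, camera adjusted p = 0.0495, adjusted p = 0.819 with an estimated correlation). H2-DMb1, which acts in peptide loading, rose by 1.62 ± 0.27 and Psmb9, an immunoproteasome subunit, by 1.61 ± 0.20 on 1 array after tMCAO, the latter not past the threshold with marked spots kept (adjusted p = 0.108). That list did not pass in 6 of 12 alternatives and 6 of 8 fits with an array left out, in which its median ran from -0.03 to 1.92. Interferon response genes did not pass (0 of 13 past the limma threshold, median 0.59, camera adjusted p = 0.0620), nor did inflammatory cytokines and enzymes (median 0.51 over 13 members, adjusted p = 0.221). Both passed when marked spots were kept (interferon response median 1.32 over 19 members, 3 of them higher, adjusted p = 0.000321, and inflammatory genes median 0.92, adjusted p = 0.00832).

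Signalling genes with an individual rise belonged to lists that did not pass. Tgfb1, a growth factor gene, rose by 2.15 ± 0.30 (adjusted p = 0.00986). The TGF-beta pathway list, with 13 measured members, had a median of -0.14, a mean of 0.43 and a test direction upward (camera adjusted p = 0.866). Of 17 epithelial-mesenchymal transition and ZEB1 repression targets, 3 rose and 1 fell (camera adjusted p = 0.761), with Snai1, a transition-promoting repressor, by 2.23 ± 0.18, the epithelial protease gene St14 by 1.29 ± 0.16 and Pard6b by -0.90 ± 0.22. Hmox1, heme oxygenase, rose by 2.88 ± 0.25 and Hk2, a hexokinase, by 1.65 ± 0.20, each on 1 array after tMCAO, the 2 of 14 hypoxia and glycolysis members past the threshold (camera adjusted p = 0.302). With marked spots kept Hk2 did not pass (adjusted p = 0.0604). The cytokine genes Osm and Cntf rose by 2.91 ± 0.34 and 1.94 ± 0.24, Cntf on 1 array after tMCAO. Zeb1 was at -0.22 on 1 array after tMCAO. With all spots kept, it was at -0.22 (95% interval -0.78 to 0.34, limma adjusted p = 0.542). The dimmer Zeb1 probe was then at -0.44 (95% interval -0.93 to 0.05, adjusted p = 0.179).

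Markers of other cells also differed in the knock-down arrays, so the changes above cannot be assigned to microglia alone. Monocyte and border macrophage markers rose in 7 of 13 members, 10 when adjusted over the list alone (median 1.55, camera adjusted p = 0.000105, adjusted p = 0.260 with an estimated correlation). The list included Cbr2, a carbonyl reductase gene, by 2.72 ± 0.24 (adjusted p = 0.00458) and Fn1, fibronectin, by 1.5 ± 0.20, 1 of its 3 probes going the opposite way. Neuron markers lay lower in all 7 measured members, 2 past the threshold and 4 when adjusted over the list alone (median -0.55, camera adjusted p = 0.0254, adjusted p = 0.405 with an estimated correlation). Past the threshold were the vesicular glutamate transporter gene Slc17a7 by -1.24 ± 0.18 (adjusted p = 0.0109) and the synaptic vesicle gene Syp by -0.68 ± 0.17 (adjusted p = 0.0433). The neuron list did not pass in 1 of 12 alternatives and 2 of 8 fits with an array left out, and the monocyte median ran from 1.23 to 2.47. Of 5 erythroid markers 3 fell, 4 when adjusted over the list alone (median -1.97, or -0.92 with a member not well above background at its bound, camera adjusted p = 0.0495, adjusted p = 0.620 with an estimated correlation). The erythroid list did not pass with marked spots kept (adjusted p = 0.12), nor in 6 of 12 alternatives, that one included, nor in 4 of 8 fits with an array left out. One of its members, the beta globin gene Hbb-b1, fell by -4.33 ± 0.31 on 1 array per time with the SE of other genes (adjusted p = 0.0301) and was at -2.50 with marked spots kept, where it did not pass (adjusted p = 0.0703), and Slc4a1 fell to a level not well above background (adjusted p = 0.0297). Outside lists that passed, the neutrophil genes Cxcr2 and Lcn2 rose by 2.77 ± 0.32 and 2.99 ± 0.45, and the endothelial and mural genes Pecam1 and Pdgfrb by 1.48 ± 0.16 and 0.84 ± 0.20. Also higher were the B cell gene Cd79b by 2.10 ± 0.33 on 1 array after tMCAO and the chemoattractant gene Rarres2 by 0.91 ± 0.16. Cd4 fell by -1.35 ± 0.20 with its second probe going the opposite way, and Kl, which encodes klotho, fell by -0.99 ± 0.25.

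**Figure D3:**
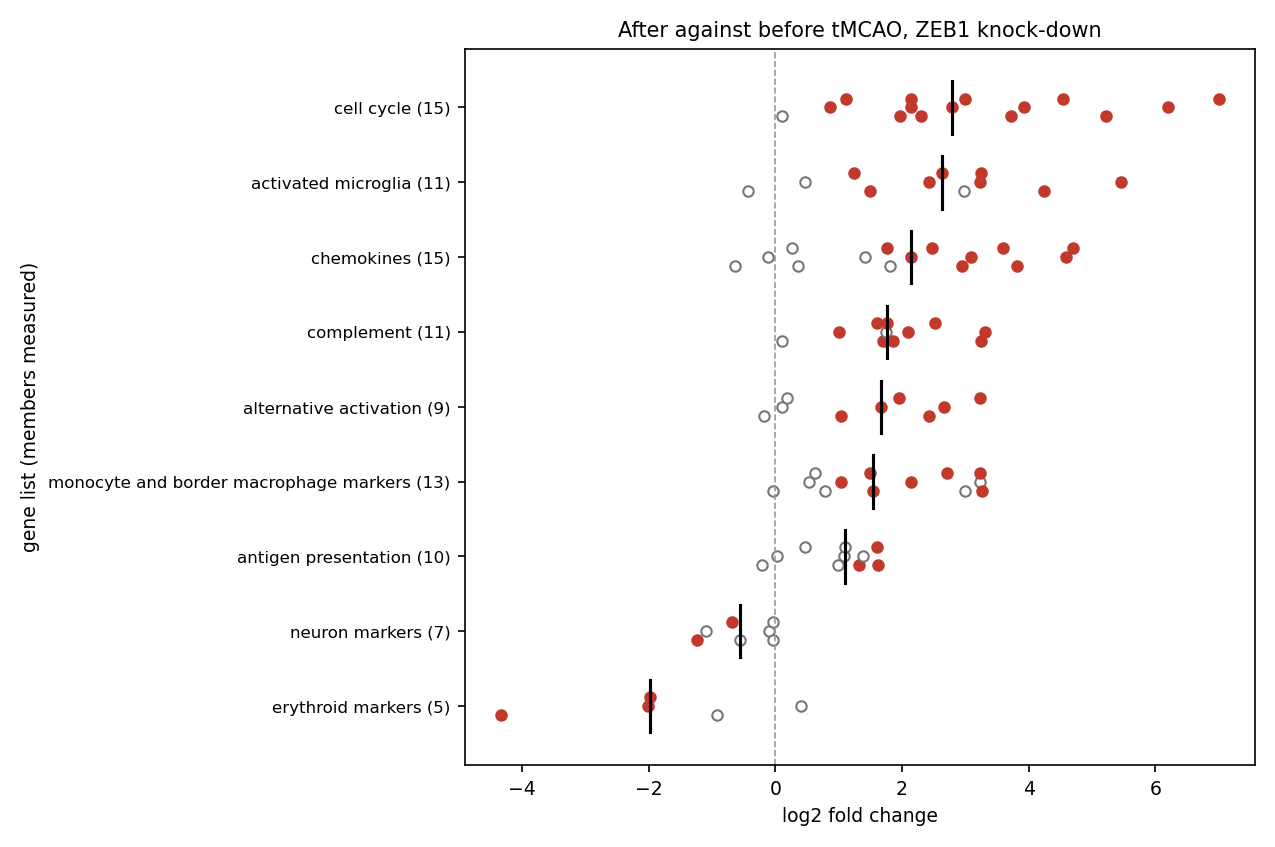
Log2 fold change of each measured member of the gene lists past the camera threshold, ZEB1 knock-down after against before tMCAO, with filled points for genes past an adjusted p of 0.05, open points for the others, vertical bars for list medians and the number of measured members in brackets. Cell cycle genes had a median of 2.79 and neuron markers a median of -0.55.

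Limma called 3940 of 24646 genes in the knock-down arrays, 2487 higher and 1453 lower after tMCAO, 2897 of them with a fitted change of at least 2-fold, and 8734 genes (35.4%) had an unadjusted p under 0.05. The largest rises were Tgm1, a transglutaminase gene, by 8.71 ± 0.48 (adjusted p = 0.00228), the matrix metalloproteinase gene Mmp3 at least 56.1-fold, the macrophage gene Cd5l at least 88.9-fold on 1 array after tMCAO, and the cyclin pseudogene Ccnb1-ps at least 52.2-fold. Mmp3, Cd5l, Bub1 and Ccnb1-ps rose from levels not well above background. The largest falls were, beside Hbb-b1, the kallikrein genes Klk1b4 at least 11.9-fold, Klk1b8 at least 18.4-fold, Klk1b3 by -4.59 ± 0.91 and Klk1b22 by -4.25 ± 0.79, and Ppargc1b, a coactivator of mitochondrial genes, by -3.44 ± 0.31 on 1 array per time. Of the 3940 calls, 3 had no replicate value in any group of the fit, Hbb-b1 and Ppargc1b among them. With marked spots kept, Klk1b4, Klk1b8, Klk1b3, Klk1b22 and Ppargc1b did not pass (adjusted p = 0.145, 0.133, 0.142, 0.162 and 0.157). The fold changes of the kallikrein genes were the same there, while Ppargc1b was at -1.9. With all spots kept, Klk1b4 ran from -7.90 to 0.16 over the arrays before tMCAO of all genotypes. The kallikrein falls therefore cannot be told apart from differences between samples before tMCAO. In 600 of the 3940 genes, a group was not well above background. The other 16 lists did not pass (camera adjusted p from 0.0620 to 0.899). Of these, 6 passed when marked spots were kept, all higher: the homeostatic, interferon and inflammatory lists, endothelial and mural markers (adjusted p = 0.00636), oligodendrocyte lineage markers (adjusted p = 0.0320) and ribosomal proteins (adjusted p = 0.0320). The count fell to 475 without knock-down before tMCAO replicate 2, to 580 without replicate 1 of that group and to 1539 without knock-down after tMCAO replicate 1. Over all 4 fits without an array of the 2 groups, the called genes, which are called for agreement between arrays, kept their direction where measured. Their fold changes were at a median of 0.956 to 1.04 of their size, with SEs at 1.17 to 1.26 times theirs. The share of higher calls was 63.1%, against 41.1% with median scaling and 45.7% with quantile normalisation.

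Whether the difference between overexpression and wild type was itself different after tMCAO was tested over the shared probes. The difference before tMCAO comes from the 8-array slide and that after tMCAO from the 4-array slide, so a constant offset of a probe cancels, but a size of the difference that depends on the slide cannot be told apart from tMCAO. Ifit2 had the largest positive difference of differences, 4.59 ± 0.37 (adjusted p = 0.0127), from a genotype difference of -0.42 before tMCAO and 4.18 after it, and was well above background in all 4 groups. Further genes past the threshold in that direction were the interferon genes Oas2, an oligoadenylate synthetase, and Ifna7, an interferon alpha, together with Vnn1, a pantetheinase, Slc28a2b, a nucleoside transporter gene, and Galnt3. In the opposite direction were Cabp2, a calcium-binding protein gene, at -2.37 ± 0.36 (adjusted p = 0.0460), and Olfr429, Afm, Psg27, Svs3b and Ttll8. Apart from Ifit2 and Cabp2, each of these genes was not well above background in 1 to 3 of the 4 groups, so their fitted sizes are not given as folds. Vnn1 was well above background only in wild type before tMCAO, so its value shows no rise after tMCAO. Slc28a2b, Galnt3 and Oas2 were not well above background in overexpression before tMCAO. Their differences may therefore come in part from the comparison before tMCAO. With normexp background correction, only Ifit2 and Oas2 of these genes passed, Cabp2 did not (adjusted p = 0.0561), and Ifna7 and Vnn1 turned direction (adjusted p = 0.982 and 0.944). Tgfb1 was at 0.69 ± 0.56 (adjusted p = 0.559).

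Among the lists, interferon response genes had a positive difference of differences in all 8 measured members (median 2.20, camera adjusted p = 1.81e-07, adjusted p = 0.658 with an estimated correlation), with 1 gene, Ifit2, past the threshold over all genes and 6 when adjusted over the list alone. Inflammatory cytokines and enzymes were positive in all 10 measured members (median 0.98, camera adjusted p = 0.000278, adjusted p = 0.658 with an estimated correlation), with 0 past the limma threshold and 2 when adjusted over the list alone. Their examples were Nos2 at 1.71 ± 0.29 (adjusted p = 0.0532) and Il1a, an interleukin gene not well above background in overexpression before tMCAO (adjusted p = 0.134). Limma called 58 of 15647 genes, 31 higher and 27 lower, with 2714 (17.3%) at an unadjusted p under 0.05, and 33 of the 58 were not well above background in at least 1 group. The share of higher calls was 53.4%, against 42.5% with normexp and 90.9% with only the groups compared, the extremes of the alternatives without left-out arrays. The other 21 lists tested did not pass (camera adjusted p from 0.112 to 0.894). When marked spots were kept, immediate early and tissue dissociation genes (median 0.86, adjusted p = 0.00620) and endothelial and mural markers (median -0.64, adjusted p = 0.0427) passed as well. The count was 0 without wild type after tMCAO replicate 1, without wild type after tMCAO replicate 2 or without wild type before tMCAO replicate 2 (limma, 1931, 2252 and 2071 genes at an unadjusted p under 0.05). It was 18 without wild type before tMCAO replicate 1, 8 without overexpression before tMCAO replicate 2, 16 without either knock-down replicate before tMCAO, and 142 without overexpression after tMCAO replicate 2. The 58 genes kept their direction wherever they were measured without an array of the 4 groups, with differences at a median of 0.980 to 1.02 of their size and SEs at 1.1 to 1.2 times theirs.

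Further contrasts of the design, wild type after against before tMCAO, overexpression after against before tMCAO, knock-down against wild type after tMCAO and overexpression against knock-down after tMCAO, set groups of different slides against each other. They were not tested. As an example, Tgfb1 lay at -0.90 ± 0.08 in wild type after tMCAO, -0.45 ± 0.81 in overexpression after tMCAO, -3.38 ± 0.54 in knock-down after tMCAO, -5.06 ± 0.04 in wild type before tMCAO, -5.31 ± 0.32 in overexpression before tMCAO and -5.53 ± 0.24 in knock-down before tMCAO (SD, n = 2, log2 relative to the 75th percentile over shared probes, with each slide normalised separately). Over 22186 genes, the SD of the difference between group means was 2.0 for wild type after against before tMCAO, 2.01 for overexpression after against before tMCAO and 1.84 for knock-down against wild type after tMCAO, all across slides. Within a slide it was 0.918 for knock-down after against before tMCAO, 0.524 for overexpression against wild type before tMCAO and 0.661 for the same genotypes after tMCAO.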

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

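Of the tests below, those on the share of other cells, on the precision of the Zeb1 probes, on pairs of arrays with none in common and the look at knock-down against wild type for the row were chosen only after the result was seen, and the others before.

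The difference between the genotypes, ZEB1 overexpression against wild type, itself differed after against before tMCAO for 58 genes (test of the difference of differences, limma adjusted p under 0.05), and this difference between groups put them here. Time and slide go together in this test, so that a genotype difference whose size depends on the slide would also appear in it. The fitted log2 differences of differences were 4.59 for Ifit2, 3.82 for Ifna7, 3.77 for Vnn1, 3.68 for Slc28a2b, 3.60 for Galnt3 and 3.45 for Oas2, and -4.43 for Olfr429, -4.33 for Afm, -3.62 for Psg27, -2.72 for Svs3b, -2.39 for Ttll8 and -2.37 for Cabp2. All but Ifit2 and Cabp2 include at least 1 group not well above background, so that their fitted values are not measured folds. Vnn1 was well above background only in wild type before tMCAO, so its value shows no rise after tMCAO. With normexp only Ifit2 and Oas2 of the 12 passed, and Ifna7 and Vnn1 turned direction (-0.020 and -0.061).

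The first pattern weighed is the rise of the interferon response genes in the overexpression arrays after tMCAO, in cells sorted for CX3CR1 with a purity that is not given in the sources used here. If a single array carried it, the median should have dropped to near 0 with that array left out. The lowest of the 4 medians was 1.5, over the 8 of 12 genes still measured without overexpression replicate 2. No single array thus carried it for the genes still measured. Genes with a value on 1 array of a group, such as Ifit2, Gbp2 and Rsad2, drop out without that array, so for them it was not tested. A larger share of lymphocytes, neutrophils or monocytes with unchanged expression per cell might raise many immune genes at once. The highest median among the 3 marker lists was 0.62 against 1.86 for the interferon genes. Without overexpression replicate 2 the highest marker median was 0.67 (monocyte markers) against 1.5. Without overexpression replicate 1, however, the lymphocyte median was 1.34 against 1.63, so that a larger share of lymphocytes in replicate 2 was not excluded. The row of the slide cannot be separated from the genotype, since 0 groups of the 4-array slide have arrays in both rows. Within these limits the values are in line with a difference in interferon-related expression between these samples, which could come from the genotype, from the cells in the individual samples or from the row.

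The second pattern is that the Zeb1 probes did not differ between the genotypes. Too few arrays might hide a change, but the highest upper bound of the 95% interval over the probes before tMCAO, overexpression against wild type, was 0.82 on the log2 scale, which excludes a doubling at these probes. Whether the probes detect an introduced or targeted sequence could not be tested, because its position is not given in the sources used here. A wrong label, a change in only part of the cells, or one in protein rather than RNA, was not tested.

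The third pattern is the large number of genes that differed after against before tMCAO in the knock-down arrays, which lie on different sides and rows of the slide. The side of the slide was tested on overexpression and wild type before tMCAO, which lie on the same pair of sides. The called genes moved in the called direction there by a median of 0.0352 of their median called change. Side alone, without an opposite effect of the row, was thus too small to account for them. The rows were exchanged in that test, so side and row might partly cancel in it, and the knock-down against wild type before tMCAO, on 1 side and in different rows, had 0 genes called by limma (2651 at an unadjusted p under 0.05). Without a single array the count of called genes fell as low as 475 of 3940, between the limits set beforehand for and against a single array as the cause. The fold changes argue against it, since over all genes those from pairs of arrays with none in common correlated at no less than 0.671 across genes. Whether a different mix of cells accounts for called genes was not tested. Monocyte and border macrophage markers were higher after tMCAO (median 1.55) and neuron markers lower (median -0.55). The called genes therefore cannot be assigned to changes within microglia.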

How the results depend on the processing

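The alternatives of keeping the marked spots, normexp on the median spot signal, unmarked probes first, list tests with the marked spots kept and list tests with an array left out were chosen after seeing the data, and the others before. Before tMCAO, the limma counts for overexpression against wild type, knock-down against wild type and overexpression against knock-down were 0 each, and 6, 1 and 4 with quantile normalisation and 1, 1 and 1 with median scaling. With an array left out they ran from 0 to 2, from 0 to 3 and stayed at 0, and the lists called from 0 to 4, from 0 to 7 and from 0 to 1. For overexpression against wild type after tMCAO, the 510 genes became 895 with marked spots kept, 336 with normexp, 321 with quantile normalisation, 297 with median scaling, 0 with no filter on dim probes (limma, 4123 at an unadjusted p under 0.05), 895 with a variance trend, 1363 at an adjusted p under 0.10 and 54 to 1079 with an array left out, and the 10 lists became 4 to 10. For knock-down after against before tMCAO, the 3940 genes became 7100 with normexp, 1715 with no filter, 5929 with a trend, 2013 with only the groups compared, 7062 at 0.10 and 475 to 3308 with an array left out, and the 9 lists became 14 with marked spots kept and 7 to 9 with an array left out. For the difference of differences, the 58 genes became 106 with marked spots kept, 105 with quantile normalisation, 34 with median scaling, 6 with no filter, 150 with probes well above background on every array, 12 with the replicate block, 141 with a trend, 11 with only the groups compared, 492 at 0.10 and 0 to 142 with an array left out (1931 to 2252 genes at an unadjusted p under 0.05 where the limma count was 0). Its 2 lists became 4 with marked spots kept, 4 with no filter and 2 to 7 with an array left out. With an estimated correlation, a version with few degrees of freedom that a list could hardly pass, camera called 0 lists in each of these 3 comparisons. Fewer arrays remain in the fits with an array left out, and a lone array is assumed to vary like the other groups. The cause was not tested otherwise.

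With the replicate number as a block, the counts were 444 for overexpression against wild type after tMCAO, 4138 for knock-down after against before tMCAO and 0 for each comparison before tMCAO (limma). Deviations of samples with the same number correlated at 0.0933 on the 4-array slide and from -0.193 to 0.260 between groups of the 8-array slide, so the numbers are not treated as pairs.

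With normexp, 20 of the 510, 63 of the 3940 and 7 of the 58 called genes took the opposite sign, and 210, 3358 and 15 stayed called. Among named genes, the following turned direction. Overexpression against knock-down before tMCAO, Cxcl1 was 0.11 with normexp and Zeb1 -0.087 with median scaling. In the difference of differences, the fitted values of Ifna7 and Vnn1 were -0.020 and -0.061 with normexp. With an array left out, Cxcl1 ran from -1.74 to 0.15 for overexpression against wild type, from -1.71 to 0.18 for knock-down against wild type and from -0.36 to 0.30 for overexpression against knock-down, all before tMCAO, Tgfb1 from -0.46 to 0.0022 for overexpression against wild type before and from -0.15 to 1.06 after tMCAO, and Zeb1 from -0.21 to 0.47 for knock-down against wild type, from -0.25 to 0.42 for overexpression against knock-down and from -0.56 to 0.12 for knock-down after against before tMCAO. The cause was not tested. Over the alternatives without left-out arrays, 317 of 365 values of named genes for overexpression against wild type after tMCAO, 531 of 573 for knock-down after against before tMCAO and 141 of 184 for the difference of differences kept direction and side of the threshold. With an array left out, 85 of 114, 288 of 375 and 102 of 179 did. No called list changed its test direction, but 3 medians changed sign: activated microglia after tMCAO (lowest -0.0049), erythroid markers (highest 0.40) and, with an array left out, antigen presentation (lowest -0.03).

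Scaling moved the centre of all genes. The median log2 fold change for knock-down after against before tMCAO was 0.04, against -0.23 with median scaling, -0.10 with quantile normalisation and 0.21 with normexp, and the share of higher calls was 63.1%, against 41.1%, 45.7% and 79.1%. The median was -0.07 and 0.12 with median scaling for knock-down against wild type before tMCAO, 0.10, -0.02 with median scaling and 0.22 with normexp for overexpression against knock-down, -0.11 and -0.27 with normexp for overexpression against wild type after tMCAO, and -0.09 and -0.42 with normexp for the difference of differences. No block for slide or scan date was possible because each design is a single slide with a single date. Normexp on the mean spot signal was not run because that column is absent. Signal over background limits the genes with a group not well above background, which have bounds only.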

Other observations

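The genes named in this part were chosen only after their values were seen, and no new test was made for them.

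In the overexpression arrays after tMCAO, further single genes were higher than in wild type. The type I interferon genes Ifna7 and Ifna5 rose at least 4.37-fold and 4.84-fold from wild type levels not well above background (limma adjusted p = 0.00329 and 0.0138), and Oas3, an oligoadenylate synthetase, at least 13.8-fold (adjusted p = 0.0138). Socs1, an inhibitor of cytokine signalling, rose by 2.74 ± 0.34 (adjusted p = 0.0222), and Cd274, which encodes an immune checkpoint ligand, by 2.44 ± 0.33. Acod1, an itaconate-producing enzyme, rose by 2.50 ± 0.34 (adjusted p = 0.0273), against 2.84 ± 0.59 before tMCAO, where it did not pass (adjusted p = 0.242). Lower were Myh11, a smooth muscle myosin, by -1.86 ± 0.25 (adjusted p = 0.0196), and Gja4, a vascular connexin, by -1.50 ± 0.26 (adjusted p = 0.0385).

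In the knock-down arrays, single genes higher after than before tMCAO included Timp1, an inhibitor of metalloproteinases, by 4.78 ± 0.28 (adjusted p = 0.00228), Col3a1, a fibrillar collagen, by 3.51 ± 0.36 (adjusted p = 0.00562), and Lox, which cross-links collagen, by 3.27 ± 0.42 (adjusted p = 0.00869). The macrophage receptor gene Vsig4 rose by 5.11 ± 0.68 and the chemokine receptor gene Ccr1 by 4.94 ± 0.56. Lower were Adora2a, an adenosine receptor, by -1.62 ± 0.15 (adjusted p = 0.00473), Pde10a by -1.63 ± 0.17 (adjusted p = 0.00855) and Drd1, a dopamine receptor, by -1.30 ± 0.25 (adjusted p = 0.0232). Drd2 and Tac1, expressed like these 3 in the striatum, were at -0.21 and -0.37 and did not pass (adjusted p = 0.776 and 0.190).

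Single genes typical of pituitary and salivary gland differed between replicates of a group, and whether tissue from outside the brain was carried over was not tested. In the overexpression arrays before tMCAO, with all spots kept, Gh lay at -1.42 in replicate 1 and 4.39 in replicate 2, Prl at -1.68 and 3.08, and Klk1b4 at -7.90 and 0.16 (log2 relative to the 75th percentile of the array). Klk1b4 lay at -5.96 and -2.95 in wild type before tMCAO and at -2.74 and -0.99 in knock-down before tMCAO. In knock-down after tMCAO it lay at -7.67 and -7.85, not well above background.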
